A study of Mus musculus with 9 samples.

How the data were processed

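The data are raw read counts per gene of 9 bulk RNA-seq libraries from basophils grown from mouse bone marrow, deposited by the authors as a single table of 35673 gene symbols. Per the labels' protocols, polyadenylated RNA was captured on oligo-dT beads, copied to cDNA, tailed, and amplified over the whole transcriptome with the TAS-Seq procedure, and the amplified cDNA was enzymatically fragmented, indexed and sequenced on a NovaSeq instrument. Amplification of this kind before fragmentation can make a library's yield depend on transcript length, and no molecular identifiers are mentioned in the labels, so counts may include amplification copies. The submitters' processing notes name cutadapt 4.1, Bowtie2 2.4.5 and the mouse build GRCm38, with no role or order; the counting tool, its annotation and its use of strand are not given in the sources used here. Bowtie2 is not a spliced aligner, and whether reads were set against the genome or against transcripts is not given either. The values were whole numbers whose totals differed between libraries, from 6261446 to 38098584, as raw counts do. No symbol was blank, and every column belonged to a labelled sample. Symbols were matched to the GENCODE vM21 annotation of GRCm38 for positions, transcript lengths and overlaps: 34336 matched, and 20668 of 21341 tested genes (96.8%) had a length. Where a pair of genes shares exonic sequence on either strand, or is nearly identical, counts may hold reads of both.

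Groups and replicate numbers were taken from the sample titles: resting (PBS with DMSO), stimulated (IL-3 and IL-33 with DMSO) and difamilast (IL-3 and IL-33 with difamilast), 3 libraries each. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, statmod 1.5.0) on the deposited counts with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and robust dispersion, in a single fit of all 9 libraries with 6 residual degrees of freedom and no covariate. The comparisons were stimulated against resting, difamilast against stimulated, and difamilast against resting. Adjusted p-values are Benjamini-Hochberg over all 21341 tested genes, and a gene is called at 0.05; log2 fold changes carry the standard error of the fit. The common biological coefficient of variation was 0.156. Levels are TMM-normalised CPM (counts scaled to effective library totals), as mean ± SD over 3 libraries. At the depths here, 99.9% of the counts of resting replicate 1, the lowest share, fell on tested genes.

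Tests, lists, named genes and most alternatives were fixed before the data were examined. The 27 lists comprise 16 pathway lists (cytokines and growth factors; chemokines; NF-kB feedback and target genes; IL-3 receptor and STAT5 target genes; MAPK feedback and immediate early genes; cAMP and CREB responsive genes; cAMP pathway components; lipid mediator and histamine enzymes; secretory granule and surface activation genes; MYC targets and ribosome biogenesis; type I interferon stimulated genes; cell cycle; unfolded protein and integrated stress response; cholesterol synthesis; glycolysis; p53 targets and apoptosis). The other 11 hold markers of basophils, mast cells, neutrophils, monocytes and macrophages, dendritic cells, eosinophils, NK and T cells, B cells, erythroid cells and megakaryocytes, progenitors, and stromal and endothelial cells. Some genes stand in more than 1 list. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Members were also called with adjustment over the list alone. The named genes are a fixed panel of 16; the 5 largest rises and 5 largest falls among called genes with no overlap between replicates and at least 10 CPM in the higher group, without predicted genes, pseudogenes and ribosomal protein genes; and up to 3 called members of each list with the smallest p, or 2 members of a list with none called. Some genes that this rule names are not reported here.

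The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a fit of only the 2 groups compared, the replicate number as a block, limma-voom, and each library left out in turn. Removal of a lowess trend (span 0.3) of log2 CPM (prior count 2) with log2 transcript length, and thinning every library to the shallowest total, were added after the data had been seen. The overlap of the stimulation and difamilast calls was set beside independent lists of the same sizes and beside 20 simulations of 9 libraries with nothing changed, since both comparisons use the stimulated libraries. The edgeR steps were tested on simulated counts drawn from the means and library sizes of 21341 genes. Changes of 1.5-fold, 2-fold and 4-fold were planted in 67, 67 and 66 genes, with no length trend between libraries. The stimulation comparison called far more genes than that, so the rates that follow need not hold for the real comparisons. For stimulation, changes of 1.5-fold, 2-fold and 4-fold were recovered in 16.4%, 62.7% and 83.3% of cases and 4.42% of calls were false; for difamilast these were 25.4%, 62.7%, 93.9% and 4.72%. Library shares were compared with two-sided exact permutation tests, which for 3 against 3 cannot go below 0.1. Bootstrap ranges are 2.5 to 97.5 percentiles over resampled genes, not libraries, so they hold no spread between samples.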

Results

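Gene expression was measured by bulk RNA sequencing in mouse basophils, rare granulocytes that release histamine, lipid mediators and type 2 cytokines. The cells came from cultures of wild-type C57BL/6J bone marrow kept for 7 days in 0.3 ng/mL interleukin-3 (IL-3), from which cells carrying CD49b were taken with magnetic particles. Portions of 10000 cells were then held for 4 hours in 1 of 3 conditions, with 3 libraries each. Resting cells received PBS and the vehicle DMSO. Stimulated cells received IL-3 and IL-33 at 10 ng/mL each with DMSO; IL-33 is an alarmin cytokine that signals through the ST2 receptor. The last group received the same cytokines with 3 µM difamilast, an inhibitor of phosphodiesterase 4 (PDE4), the enzyme family that degrades the second messenger cAMP in immune cells. Resting cells with difamilast were not analysed here, so the comparisons speak of the inhibitor in stimulated cells.

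Total counts per library were 10838055, 14795353 and 6261446 for resting replicates 1 to 3, 11798711, 38098584 and 35451077 for stimulated replicates, and 30299575, 30075599 and 24812305 for difamilast replicates. On average the resting libraries were the shallowest. The 10 most abundant genes took 13.2% ± 2.47 (SD, n = 3) of counts in resting, 24.4% ± 0.677 in stimulated and 22.6% ± 2.93 in difamilast libraries. Mitochondrially encoded genes took 2.32% ± 0.457, 1.57% ± 0.0856 and 1.27% ± 0.127, with no overlap between groups, which gives p = 0.1 for each neighbouring pair of groups in a two-sided exact permutation test, the smallest that 3 against 3 libraries can give. A ribosomal RNA gene, CT010467.1 on chromosome 17 from 39846353 to 39848827, took between 5.37% and 11.4% of a library. Libraries of the same group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 4.42 to 47.3, so none was taken for a library deposited more than once. That test covers the counting error of reads only, and since amplified reads without molecular identifiers are not independent molecules it does not show that the libraries came from separate RNA. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

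The comparison of stimulated with resting cells asks what IL-3 and IL-33 did to basophils in vehicle. Among called genes that reached 10 CPM (counts scaled to library totals) and whose replicates did not overlap, the 5 largest rises were all in cytokine genes. Csf2, which encodes the growth factor GM-CSF, was 24.1-fold higher, Il13 22.8-fold, Il6 19.1-fold, and Il9 18.9-fold, and Lta, which encodes lymphotoxin alpha, was 23.7-fold higher. In level, Il6 went from 321 ± 26.7 to 6124 ± 160.0 CPM (SD, n = 3) and Il13 from 39.3 ± 3.11 to 897 ± 76. The 5 largest falls by the same rule were in Nap1l5 (21.7-fold lower), S1pr1, a receptor that guides leukocyte egress (12.8-fold), Gdf15 (11.9-fold), Nxpe4 (11.5-fold) and Samd13 (9.09-fold). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6770 of 21341 tested genes changed, 3273 higher and 3497 lower, and 1600 and 1341 of these changed at least 2-fold. Adjusted p-values of these 10 genes ran from 6.6e-12 for Il6 to 2.3e-06 for Gdf15.

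Of 24 tested cytokine and growth factor genes, 21 rose and 1 fell with stimulation; adjusted over the list alone, 21 rose and 2 fell. Among them, the type 2 cytokine Il4 (chromosome 11, 53602982 to 53618669) rose 5.43-fold, Il13 (chromosome 11, 53631324 to 53634702) lies close to it, Il1a rose 14-fold, and Areg, the epidermal growth factor receptor ligand amphiregulin, rose 8.47-fold. Tnf had a log2 fold change of 0.70 ± 0.24 (SE; adjusted p = 0.0362), and it passed neither without resting replicate 1 (adjusted p = 0.24) or 2 (0.154), nor without stimulated replicate 1 (0.108), 2 (0.0597) or 3 (0.108), nor in a fit of these 2 groups alone (0.0709). Over every alternative its adjusted p ran from 6.45e-05 to 0.24. Of 20 chemokine genes, 15 rose and 1 fell, the same counts as adjusted over the list alone. Ccl3 reached 11293 ± 1209 CPM from 740.3 ± 147, Ccl4 rose 8.16-fold, the neutrophil attractants Cxcl2 and Cxcl3 rose 14.3-fold and 12.2-fold, and the monocyte attractant Ccl7 rose 18.7-fold. Both lists stood above the other genes in camera, limma's competitive set test (adjusted p = 1.19e-33 and 5.62e-25), also with an estimated correlation (adjusted p = 0.00166 and 0.0228).

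Genes known to respond to NF-kB, the transcription factor family downstream of ST2, rose in 28 of 32 cases and fell in 3 (adjusted over the list alone, 29 and 3). Traf1, a signalling adaptor, rose 16.4-fold, Nfkbia, which encodes the NF-kB inhibitor IkBa, 5.97-fold, and Ptgs2, the inducible cyclooxygenase, 8.12-fold. Of 20 IL-3 receptor and STAT5 target genes, 14 rose and 3 fell (adjusted over the list alone, 15 and 4), with Il2ra 15.5-fold, the survival kinase Pim2 11.7-fold and the survival factor Bcl2l1 8.64-fold higher. These 2 lists passed camera (adjusted p = 1.74e-42 and 5.98e-35) and passed it with an estimated correlation (adjusted p = 0.00099 for each). The MAPK feedback and immediate early list had 18 risen and 3 fallen of 26 (adjusted over the list alone, 19 and 3), among them Phlda1 (10.3-fold) and the transcription factors Egr1 (7.57-fold) and Egr2 (9.26-fold), whereas Fos was 4.35-fold lower. Type I interferon stimulated genes rose in 29 of 30 cases (30 adjusted over the list alone), among them the nucleic acid sensor Zbp1 (5.9-fold), Isg20 (6.11-fold) and Rtp4 (3.69-fold). The MAPK and interferon lists passed camera (adjusted p = 5.66e-11 and 2.33e-24) and neither call held with an estimated correlation (adjusted p = 0.127 and 0.102 with an estimated correlation). In the other camera settings the adjusted p ran from 3.29e-12 to 5.39e-09 and from 1.49e-38 to 1.51e-21.

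Cell cycle genes moved the other way. Of 30, 24 fell and 1 rose (adjusted over the list alone, 26 and 1; camera adjusted p = 2.24e-08, and adjusted p = 0.0228 with an estimated correlation). The centromere protein gene Cenpf was 4.01-fold lower, the proliferation marker Mki67 2.61-fold and the mitotic kinesin Kif11 2.77-fold. Components of the cAMP pathway fell in 15 of 35 cases and rose in 5 (adjusted over the list alone, 16 and 5), and cAMP and CREB responsive genes fell in 12 of 30 and rose in 8 (13 and 8 adjusted over the list alone). Neither list passed camera (adjusted p = 0.335 and 0.72). The members parted: the protein kinase A subunit gene Prkacb was 5.68-fold lower, the phosphodiesterase genes Pde4a and Pde4d were 2.24-fold and 2.78-fold lower, while Pde4b was 5.32-fold, the adenosine receptor gene Adora2b 9.68-fold, the orphan nuclear receptor gene Nr4a3 6.3-fold and Maff 4.18-fold higher.

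Basophil identity genes rose in 17 of 26 cases and fell in 4 (adjusted over the list alone, 19 and 4; camera adjusted p = 2.46e-07, and adjusted p = 0.014 with an estimated correlation). The glutamate receptor gene Grm6 rose 4.42-fold, Hgf 2.9-fold, the chemokine gene Ccl9 3.68-fold, the basophil protease gene Mcpt8 2.41-fold, the ST2 gene Il1rl1 2.4-fold and the IL-3 receptor gene Il3ra 1.46-fold. Hdc, the histamine-forming enzyme, had a log2 fold change of 0.25 ± 0.13 (SE; adjusted p = 0.162), and it passed without resting replicate 1 (0.39, adjusted p = 0.00102; 0.00102 to 0.577 over every alternative). The secretory granule and surface activation list held 7 genes that rose and 6 that fell of 22 (adjusted over the list alone, 10 and 6), with the activation marker Cd69 15.7-fold, the granule proteoglycan Srgn 4.84-fold and granzyme B (Gzmb) 2.94-fold higher. Its camera call (adjusted p = 0.0485) was lost with an estimated correlation (adjusted p = 0.221), with RLE scaling (0.0533) and without resting replicate 2 (0.0614) or 3 (0.0597), stimulated replicate 3 (0.0583) or difamilast replicate 2 (0.0548). Lipid mediator and histamine enzymes rose in 4 and fell in 5 of 15 cases (adjusted over the list alone, 5 and 5; camera adjusted p = 0.92, with a median log2 fold change of -0.19 although the test pointed up), with the lipoxygenase gene Alox15 3.09-fold and the phospholipase gene Pla2g7 1.92-fold lower.

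Markers of other cells that a CD49b selection from bone marrow could hold were tested the same way. Monocyte and macrophage markers fell in 8 of 18 cases and rose in 1 with stimulation (adjusted over the list alone, 10 and 1; camera adjusted p = 0.0674). That list passed without resting replicate 1 (adjusted p = 0.0187), without stimulated replicate 1 (adjusted p = 0.0472) and after removal of the length trend (adjusted p = 0.0306; 0.0187 to 0.132 over camera's alternatives at the preset correlation). With an estimated correlation it did not pass (adjusted p = 0.28). The most abundant markers of that list were Lyz2, which encodes a lysozyme, and Apoe. Lyz2 lay at 3957 ± 483 CPM in resting, 2736 ± 36.3 in stimulated and 2621 ± 87.9 in difamilast libraries, and Apoe at 1964 ± 294, 1378 ± 90 and 1346 ± 60.9. Cd74, the most abundant of the dendritic cell and antigen presentation markers, lay at 1454 ± 190.0, 1517 ± 56.3 and 1698 ± 61.9, beside 1434 ± 415, 3455 ± 229 and 2802 ± 429 for Mcpt8. Bulk counts do not tell which cells held a transcript, so the changes reported here, with stimulation or difamilast, cannot be assigned to basophils alone. The monocyte markers Cx3cr1 and Csf1r were 3.37-fold and 1.76-fold lower. Mast cell markers rose in 4 and fell in 3 of 12 cases, among them Tph1, the serotonin-forming enzyme (5.48-fold higher), and the serotonin transporter gene Slc6a4 (3.79-fold higher); adjusted over the list alone the counts were the same, and camera gave adjusted p = 0.0798. Haemoglobin genes took at most 0.00729% of the counts of a library.

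**Figure D1:**
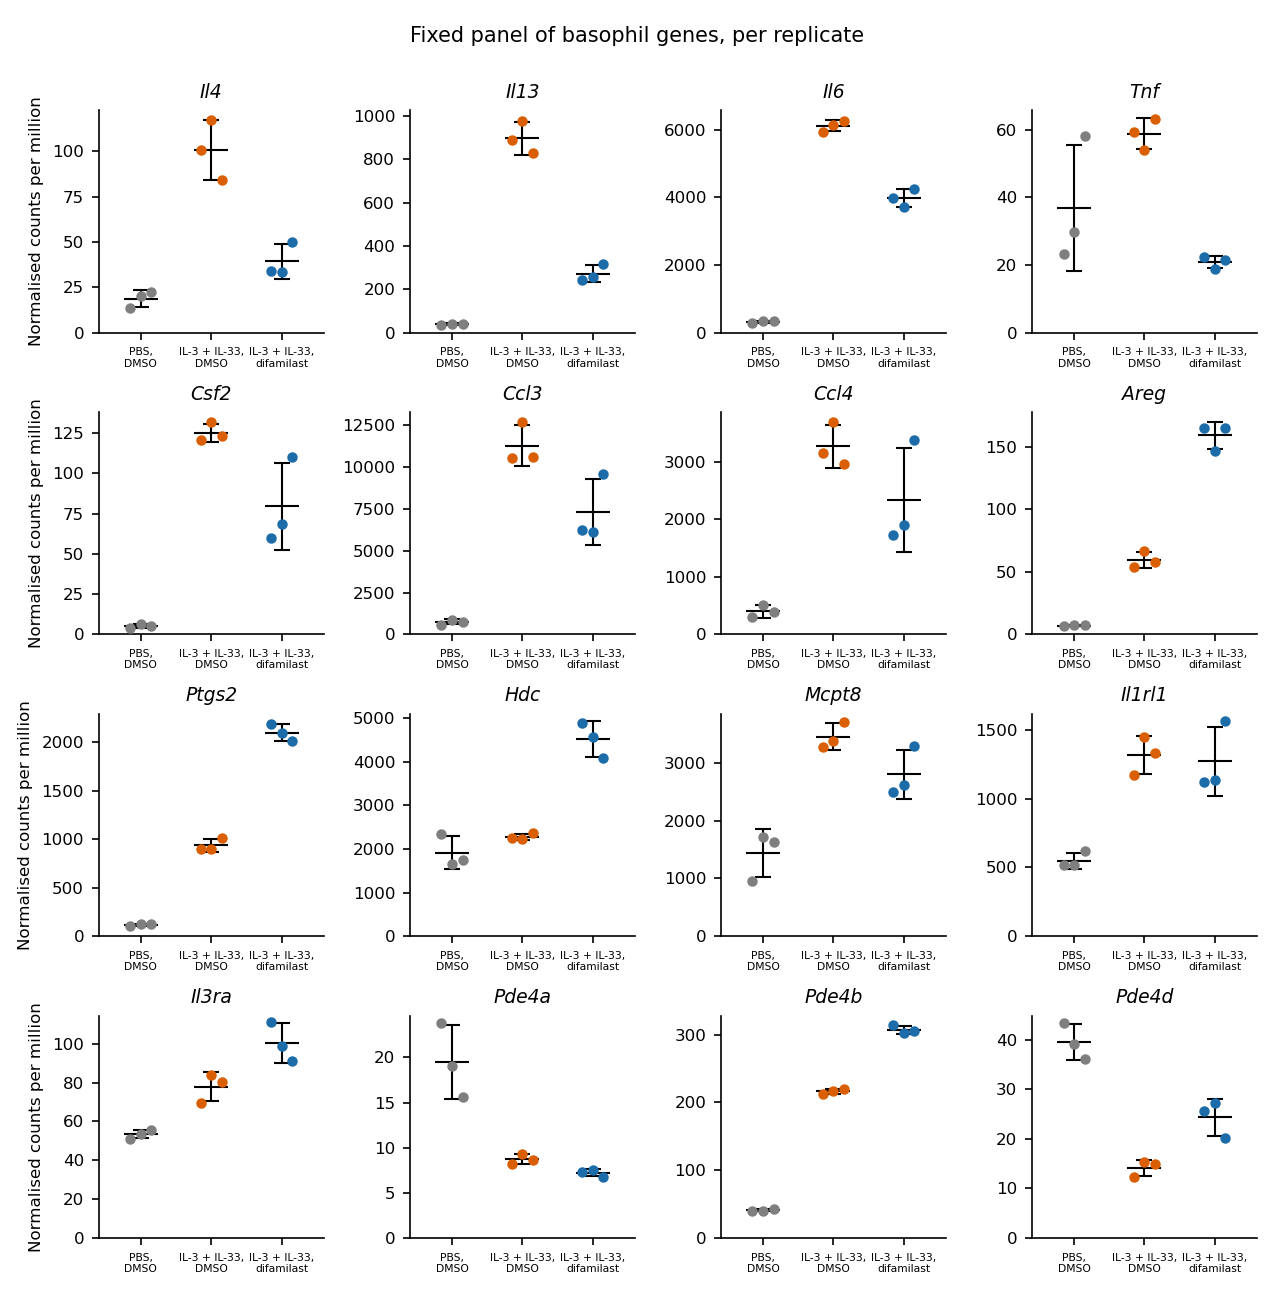
Normalised CPM of 16 basophil genes in resting, stimulated and difamilast libraries; points are the 3 libraries of a group, and bars give the mean and SD. Il4 and Il13 lay lower and Areg, Ptgs2 and Hdc higher in all 3 difamilast libraries than in any stimulated library without it, while Ccl4 and Mcpt8 of difamilast replicate 3 lay within the range of the stimulated libraries.

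The comparison of difamilast with vehicle in stimulated cells asks what the PDE4 inhibitor changed in activated basophils, and the study's title names inflammatory mediators as its object. Of the fixed panel, Il13 fell from 897 ± 76 to 272 ± 40.9 CPM (SD, n = 3), 3.3-fold lower, Tnf was 2.82-fold, Il4 2.57-fold and Il6 1.54-fold lower. Other transcripts of the panel were higher, those of enzymes that form mediators among them. Ptgs2 went from 938 ± 66.7 to 2101 ± 86.9 CPM, Areg from 59.5 ± 6.73 to 159 ± 10.5, and Hdc from 2277 ± 70.9 to 4518 ± 412. By the rule used for stimulation, the 5 largest falls were in Edn1, which encodes the peptide endothelin-1 (6.39-fold lower), Il13, the growth factor gene Pdgfa (3.03-fold), the transcription factor Egr3 (2.98-fold) and Tnf. Among the 5 largest rises were Ptprn (5.33-fold higher), Hid1 (5.05-fold), Thbs1, which encodes thrombospondin-1 (4.98-fold), and Dio2, the thyroid hormone activating deiodinase (4.73-fold). Adjusted p-values of the genes named here ran from 1.48e-06 for Il13 to 0.00174 for Il6 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 735 of 21341 genes changed, 471 higher and 264 lower, and 153 and 81 of these changed at least 2-fold. The balance of higher to lower calls moved with the libraries and the fit: it was 540 and 598 without difamilast replicate 3, 870 and 823 without resting replicate 1, 831 and 842 in a fit of these 2 groups alone and 689 and 662 without a filter on low counts. The share of higher calls was 64.1% in the fit of all libraries and between 47.5% and 74.4% over the alternatives, highest without difamilast replicate 2. The total moved too. It was 1693 without resting replicate 1, 379, 387 and 446 without stimulated replicates 1, 2 and 3, 403, 347 and 1138 without difamilast replicates 1, 2 and 3, 1115 with DESeq2, 1351 without a filter on low counts and 1673 in a fit of these 2 groups alone.

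cAMP and CREB responsive genes were the list that rose most clearly with difamilast. Of 30, 13 rose over all genes and none of the others fell; adjusted over the list alone, 18 rose and 2 fell. Camera gave adjusted p = 4.54e-29, and adjusted p = 0.000336 with an estimated correlation, the single list of 27 that held. The kinase gene Sik1, a known CREB target, went from 12.4 ± 1.44 to 51.5 ± 2.37 CPM (SD, n = 3), Crem, a cAMP-inducible repressor of CREB targets, rose 2.76-fold, the G protein regulator Rgs1 2.67-fold and Vegfa 2.15-fold. Components of the cAMP pathway rose in 6 and fell in 2 of 35 cases (adjusted over the list alone, 8 and 3), among them Crem and the adenosine receptor gene Adora2a (1.85-fold higher). That list's camera call (adjusted p = 0.00864) was lost with an estimated correlation (adjusted p = 0.505), in fry's directional test (0.123) and after removal of the trend with transcript length (0.0644). Among the genes of the drug's own target family, Pde4b was 1.42-fold and Pde4d 1.71-fold higher, and Pde4a had a log2 fold change of -0.28 ± 0.17 (SE; adjusted p = 0.511). Pde4d did not pass without stimulated replicate 1 (adjusted p = 0.0534) or difamilast replicate 2 (adjusted p = 0.0586), and over every alternative its adjusted p ran from 4.99e-05 to 0.0586.

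Of 20 chemokine genes, 4 fell with difamilast over all genes tested and 10 fell adjusted over the list alone, and the median log2 fold change was -0.58. The camera call (adjusted p = 8.34e-09; 2e-12 to 2.96e-07 in the other camera settings) was lost with an estimated correlation (adjusted p = 0.263). The monocyte attractants Ccl2 and Ccl7 were 2.73-fold and 2.63-fold lower, and Ccl5 was 2.29-fold lower, although Ccl5 did not pass without resting replicate 1 (adjusted p = 0.0721; 5.5e-17 to 0.0721 over every alternative). Ccl3 (log2 fold change -0.62 ± 0.18 SE, adjusted p = 0.0714), Ccl4 (-0.48 ± 0.22, adjusted p = 0.335) and the cytokine gene Csf2 (-0.66 ± 0.19, adjusted p = 0.0846) did not pass. These transcripts are short (766, 660 and 800 bases), and short transcripts as a class lay lower with difamilast. Over genes averaging at least 10 CPM, the median log2 fold change was -0.31 under 750 bases and -0.39 from 750 to 1000. Falls of short transcripts may hold part of this shift, those of Il4, Ccl2, Ccl7 and Ccl5 (590, 813, 801 and 532 bases) among them. Within the difamilast group, replicate 3 held more of short transcripts than the group mean. In median log2 CPM, genes with transcripts under 750 bases deviated in it by 0.43, against -0.22 and -0.19 in replicates 1 and 2, and those of 750 to 1000 bases by 0.27, against -0.20 and -0.07. Without replicate 3, 11 chemokine genes fell, and Ccl3 (adjusted p = 0.00389), Ccl4 (0.0144) and Csf2 (0.00175) passed; with the length trend removed, 7 fell and 1 rose. The log2 fold changes were then smaller, -0.46 for Ccl3 (adjusted p = 0.0198), -0.51 for Csf2 (adjusted p = 0.031) and -0.32 for Ccl4, which did not pass (adjusted p = 0.271). Over every alternative the adjusted p ran from 2.07e-06 to 0.364 for Ccl3, 0.00208 to 0.786 for Ccl4 and 0.00021 to 0.402 for Csf2.

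Cytokine genes went both ways, with 4 that rose and 5 that fell of 24 (adjusted over the list alone, 7 and 6; camera adjusted p = 0.85, pointing down against a median log2 fold change of 0.02). Il13, Tnf, Il4 and Il6 fell, Areg, Vegfa and Osm rose, and Il9 had a log2 fold change of -0.24 ± 0.19 (SE; adjusted p = 0.639), but -0.57 without difamilast replicate 3, where it passed (adjusted p = 0.0219; 0.0219 to 0.954 over every alternative). Oncostatin M (Osm) went from 1393 ± 104 to 2435 ± 295 CPM. NF-kB feedback and target genes also parted, with 6 higher and 5 lower of 32 (adjusted over the list alone, 9 and 9; camera adjusted p = 0.466, pointing up against a median of -0.06). The adhesion molecule gene Icam1 was 2.21-fold lower, and the chemokine-binding receptor gene Ccrl2 3.22-fold and Ptgs2 2.24-fold higher. STAT5 target genes rose in 4 and fell in 1 of 20 cases (adjusted over the list alone, 4 and 3; camera adjusted p = 0.531), among them Osm and the near-identical receptor genes Csf2rb (1.67-fold) and Csf2rb2 (1.64-fold), whose reads the counting may have split. Immediate early and MAPK feedback genes rose in 6 and fell in 2 of 26 cases (adjusted over the list alone, 8 and 6): Fos was 3.39-fold, Fosl2 2.87-fold and the phosphatase gene Dusp1 2.7-fold higher. The camera call (adjusted p = 0.0115) was lost with an estimated correlation (adjusted p = 0.625), in fry's directional test (0.138) and without stimulated replicate 2 (0.105) or difamilast replicate 1 (0.0933).

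Type I interferon stimulated genes fell in 5 of 30 cases (8 adjusted over the list alone), 11 without difamilast replicate 3 and 7 with the length trend removed; Ifi205, a member of a family of similar genes, was 1.96-fold lower. The camera call (adjusted p = 1.09e-07; 4.28e-10 to 1.46e-05 in the other camera settings) was lost in fry's directional test (0.138) and with an estimated correlation (adjusted p = 0.505). Lipid mediator and histamine enzymes rose in 3 and fell in 2 of 15 cases, also adjusted over the list alone (camera adjusted p = 0.187), with Ptgs2, Hdc and the arachidonate-releasing phospholipase gene Pla2g4a (2.06-fold) higher. Of secretory granule and surface activation genes, 3 rose and 1 fell of 22 (adjusted over the list alone, 5 and 2; camera adjusted p = 0.745): Cd69 was 2.22-fold lower, Gzmb 1.8-fold and the granule trafficking gene Rab27b 1.76-fold higher. Basophil identity genes rose in 2 and fell in 3 of 26 cases (adjusted over the list alone, 4 and 3; camera adjusted p = 0.466), with the IgE receptor subunit gene Ms4a2 1.75-fold lower. The IL-33 receptor gene Il1rl1 (log2 fold change -0.05 ± 0.14 SE, adjusted p = 0.913), Il3ra (0.37 ± 0.11, adjusted p = 0.101) and Mcpt8 (-0.30 ± 0.18, adjusted p = 0.473) did not pass. Il3ra passed without resting replicate 1 (adjusted p = 0.0178), without difamilast replicate 3 (adjusted p = 0.0493), with DESeq2 (0.0251) and in a fit of these 2 groups alone (0.0299; 0.0178 to 0.44 over every alternative). Mast cell markers fell in 3 of 12 cases, also adjusted over the list alone, with Slc6a4 2.48-fold and the transcription factor Mitf 1.96-fold lower; the camera call (adjusted p = 0.000199) was lost with an estimated correlation (adjusted p = 0.0685). No cell cycle gene of 30 was called by edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and camera gave adjusted p = 0.466.

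**Figure D2:**
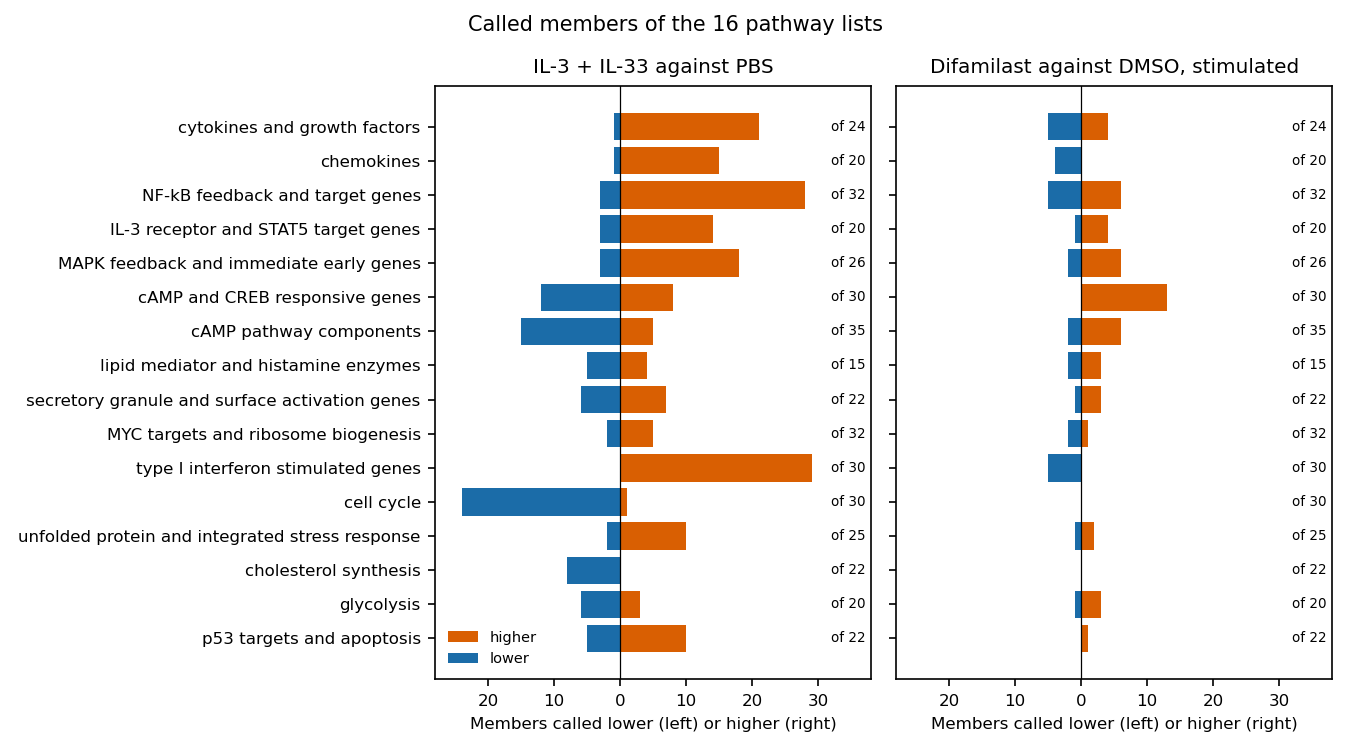
Members of 16 pathway lists called higher (right) or lower (left) for stimulation and for difamilast, as numbers of genes; the number tested stands at the right of each panel. With stimulation 29 of 30 interferon genes were higher and 24 of 30 cell cycle genes lower, and with difamilast 13 of 30 cAMP and CREB responsive genes were higher.

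A further comparison asked how far difamilast undid what stimulation had done. Of the genes that stimulation raised, 196 were lowered by difamilast, among them Il13, Il4, Il6, Cd69, Icam1, Edn1 and Batf3, a dendritic cell transcription factor that went from 1.49 ± 0.867 to 9.4 ± 0.984 and back to 1.81 ± 0.907 CPM (SD, n = 3). Of the genes that stimulation lowered, 177 were raised by difamilast, among them Sik1, Fos, Rgs1, Crem and S1pr1. A further 158 genes were raised by both, among them Areg, Ptgs2, Osm, Pde4b and Nr4a3, and 18 were lowered by both. Independent lists of these sizes would share 40.5, 77.2, 72.2 and 43.3 genes. In 20 simulations with nothing changed these counts were 0, but almost no gene was called there, so they do not show how many the shared libraries could add. The stimulated libraries enter both comparisons with opposite sign, and 3 libraries cannot be divided into parts of 2, so part of the excess of genes raised then lowered, or lowered then raised, may come from the shared libraries. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.0901 against -0.0477 in simulations, a difference of -0.0424; the correlation was -0.24 against -0.475.

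**Figure D3:**
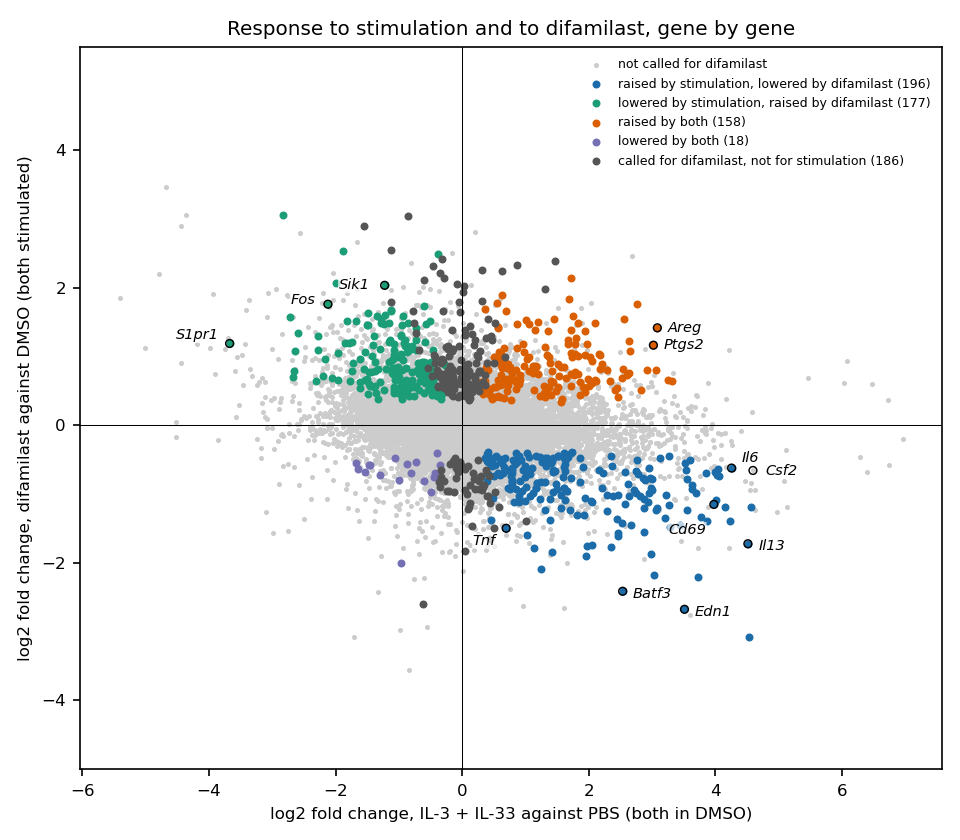
Log2 fold change with difamilast against log2 fold change with stimulation for each tested gene, coloured by the calls in both comparisons. The 196 genes raised by stimulation and lowered by difamilast include Il13, Cd69 and Edn1, and the 158 raised by both include Areg and Ptgs2.

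Difamilast left most of the response in place. In cells with difamilast and cytokines against resting cells, 7001 genes differed, 3501 higher and 3500 lower. Of the 27 lists, 12 passed camera in that comparison and 6 with an estimated correlation. Il6 remained 12.4-fold, Il13 6.92-fold, Csf2 15.3-fold, Ccl3 9.91-fold and Il9 16.1-fold above resting cells, and Ptgs2 and Areg stood 18.2-fold and 22.6-fold above them; for Batf3 the log2 fold change was 0.12 ± 0.39 (SE; adjusted p = 0.847) and for Edn1 0.84 ± 0.42 (adjusted p = 0.143), which passed without resting replicate 1 (1.41, adjusted p = 0.03) or difamilast replicate 2 (1.17, adjusted p = 0.0318; 0.03 to 0.536 over every alternative). Tnf lay 1.74-fold below resting cells (adjusted p = 0.0187), a call that did not hold without resting replicate 3 (adjusted p = 0.0712) or difamilast replicate 2 (adjusted p = 0.0707). Over the 196 genes raised and then lowered, the median share of the log2 rise removed was 54.4%; 115 remained above resting cells, 77 were not called different and 4 were below. Over the 177 genes lowered and then raised, the median was 95.9%, and 98 were not called different from resting cells. These medians rest on genes picked for a change in the second comparison. Over all 3273 genes that stimulation raised, the median share removed was 5.81% and 2612 remained higher. For all 3497 that it lowered, the median share was 11.9% and 2683 remained lower. The stimulated libraries enter both fold changes of a share with opposite sign, so a positive median can arise with no drug effect. The count of 196 genes raised and then lowered was 360 without resting replicate 1, 86, 97 and 108 without stimulated replicates 1, 2 and 3, 93 and 76 without difamilast replicates 1 and 2, 327 without a filter on low counts and 380 in fits of 2 groups at a time.

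**Figure D4:**
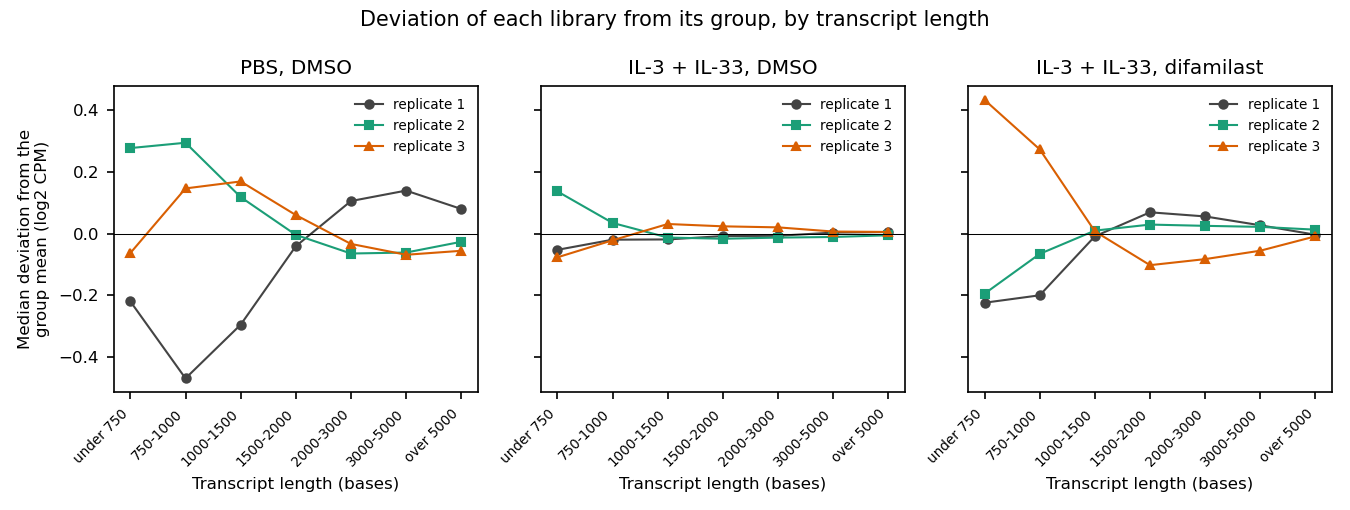
Median deviation of each library from its group mean, in log2 CPM, over genes binned by transcript length in bases, for the 3 groups. For transcripts under 750 bases difamilast replicate 3 lay at 0.43, for those of 750 to 1000 bases resting replicate 1 lay at -0.47, and the stimulated libraries stayed between -0.08 and 0.14 in every bin.

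In GRCm38, with the GENCODE vM21 annotation, Csf2 lies on chromosome 11, 54247271 to 54249667, Il6 on chromosome 5, 30013114 to 30019981, Areg on chromosome 5, 91139599 to 91148432, Ptgs2 on chromosome 1, 150100031 to 150108227, Sik1 on chromosome 17, 31844250 to 31855804 and Edn1 on chromosome 13, 42301476 to 42307990. Exons of several named genes overlap annotated exons of another gene, and how the counting treated strand is not given in the sources used here, so their counts are uncertain to that extent. Overlapping antisense genes lie at Csf2, Il1a, Il3ra, Phlda1, Pla2g7, Grm6, Cx3cr1, Csf1r, Thbs1, Dio2, Edn1, Pdgfa, Icam1, Dusp1, Crem and Myb, and genes of the same strand at Samd13, Rtp4, Pdia4, Csf2rb and Csf2rb2.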

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

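No gene called for a comparison was called in the opposite direction in any alternative. The count of genes changed by difamilast, 735, was 1115 with DESeq2, 1351 without a filter on low counts and 1673 in a fit of the 2 groups alone. The induced genes lowered, 196, were 327 and 380 in the last 2 of these. Without resting replicate 1 alone the difamilast count was 1693, against 786 and 750 without resting replicate 2 or 3. Resting replicate 1 had the widest deviations of the 9 libraries (SD 0.282), and the single fit shares its estimate of spread over all groups. Its presence thus went with fewer difamilast calls, although it is not in that comparison. The cause of the DESeq2 and unfiltered counts was not tested. Called lists numbered 11 with stimulation and 8 with difamilast by camera, 6 and 1 with an estimated correlation, 17 and 5 by fry's directional test and 27 and 21 by its mixed test, which ask other questions of a list than camera does. Leaving out each library in turn gave 5138 to 6885 genes for stimulation, 347 to 1693 for difamilast (lowest without difamilast replicate 2, highest without resting replicate 1), 5645 to 7273 for difamilast against resting cells, 76 to 360 for the induced genes lowered, 9 to 12 lists with stimulation and 7 to 10 with difamilast. Stimulation, difamilast, difamilast against resting cells and induced genes lowered kept within 1.5 times their counts with limma-voom (6700, 968, 6813 and 272) and RLE scaling (6779, 730, 7008 and 181). The same held for 2 alternatives chosen after seeing the data, removal of the length trend (7199, 968, 7583 and 275) and thinning each library to the shallowest total (5586, 618, 5564 and 158). RLE scaling moved the share of higher calls with stimulation from 48.3% to 44.1%. Replicate numbers did not pair the libraries: deviations from the group means correlated at -0.0778 to 0.108 between libraries of the same number and at -0.147 to 0.172 between others, across genes, and 0 of 9 libraries correlated best with its own number in both other groups. With the number as a replicate block the counts were 6489, 700, 6652 and 198, with 11 and 8 lists. Over named genes and all alternatives, 2369 values for stimulation kept direction and side of the threshold, 37 fell short of it and 24 newly passed it; for difamilast these were 2217, 91 and 93, and against resting cells 2370, 41 and 20. Uncalled values that changed sign numbered 17, 45 and 16. List tests that changed sign without a call numbered 11 with stimulation and 18 with difamilast. Depth limits which genes can be tested: thinning every library to the lowest total, that of resting replicate 3, reduced the number of tested genes from 21341 to 15939.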

Other observations

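Metabolic and stress genes were also measured. With stimulation, genes of the unfolded protein and integrated stress response stood at 10 higher and 2 lower of 25 (adjusted over the list alone, 11 and 3; camera adjusted p = 0.0294). That list's call was lost at adjusted p = 0.49 with an estimated correlation, and also with RLE scaling (adjusted p = 0.0533) and without resting replicate 2 (adjusted p = 0.0599; 0.016 to 0.0599 over camera's other alternatives at the preset correlation). The chaperone gene Hspa5 rose 2.05-fold, the disulfide isomerase gene Pdia4 2.34-fold and Sesn2, a stress-inducible inhibitor of mTORC1, 2.43-fold. Genes of cholesterol synthesis stood at 0 higher and 8 lower of 22 (adjusted over the list alone, 0 and 9; camera adjusted p = 0.0105), among them the sterol desaturase gene Sc5d (2.2-fold lower) and Pmvk (2.28-fold). That call was lost at adjusted p = 0.432 with an estimated correlation (0.00249 to 0.028 over camera's other alternatives at the preset correlation). MYC targets and ribosome biogenesis genes had 5 higher and 2 lower of 32 (adjusted over the list alone, 5 and 2; camera adjusted p = 0.518), with Myc itself 3.32-fold higher. Glycolysis genes had 3 higher and 6 lower of 20 (adjusted over the list alone, 3 and 6; camera adjusted p = 0.877), with camera pointing down and fry up: the glucose transporter gene Slc2a3 rose 2.36-fold and Gpi1 fell 2.54-fold. Targets of p53 and apoptosis genes had 10 higher and 5 lower of 22 (adjusted over the list alone, 10 and 5; camera adjusted p = 0.38), with the death receptor gene Fas 9.38-fold and the cell cycle inhibitor gene Cdkn1a 3.26-fold higher. With difamilast, glycolysis genes had 3 higher and 1 lower of 20 (adjusted over the list alone, 10 and 1; camera adjusted p = 3.12e-06): the lactate transporter gene Slc16a3 was 1.76-fold and Pfkfb3, a regulator of glycolytic flux, 1.71-fold higher, while Slc2a3 was 2.11-fold lower. The glycolysis call was lost at adjusted p = 0.505 with an estimated correlation and in fry's directional test (adjusted p = 0.0784), against 1.96e-08 to 0.000102 over camera's other alternatives at the preset correlation. MYC targets had 1 higher and 2 lower of 32 (adjusted over the list alone, 2 and 9; camera adjusted p = 5.07e-05), and a median log2 fold change of -0.27. The call of MYC targets was lost at adjusted p = 0.123 with an estimated correlation (6.23e-06 to 0.00256 over camera's other alternatives at the preset correlation). Unfolded protein genes had 2 higher and 1 lower of 25 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.204), and the list passed without difamilast replicate 3 (adjusted p = 0.0159; 0.0159 to 0.55 over camera's other alternatives at the preset correlation), while all libraries gave adjusted p = 0.695 with an estimated correlation. With difamilast p53 targets had 1 higher and 0 lower of 22 (adjusted over the list alone, 1 and 0; camera adjusted p = 0.677), the called member being the pro-apoptotic gene Bcl2l11 (1.66-fold). Of 22 cholesterol synthesis genes, 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.85).

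Markers of other blood and marrow cells showed mixed changes. With stimulation the neutrophil list had 5 higher and 3 lower of 18 (adjusted over the list alone, 5 and 3; camera adjusted p = 0.818), with a median log2 fold change of -0.10 and a mean of 0.11; Lcn2, an antibacterial lipocalin, rose 5.36-fold and Padi4 fell 2.63-fold. The dendritic cell list had 2 higher and 4 lower of 13 (adjusted over the list alone, 3 and 5; camera adjusted p = 0.863), with a median of -0.05, a mean of 0.11 and camera pointing down. The progenitor list had 4 higher and 4 lower of 12 (adjusted over the list alone, 6 and 4; camera adjusted p = 0.972), with a median of 0.16, a mean of -0.06 and camera pointing down and fry up; the transcription factor gene Erg was 6.45-fold lower and Gfi1b 3.08-fold higher. Eosinophil markers had 1 higher and 3 lower of 7 (adjusted over the list alone, 1 and 3; camera adjusted p = 0.138), among them the eotaxin receptor gene Ccr3 (4.29-fold lower). The NK and T cell list had 3 higher and 1 lower of 16 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.72), the B cell list 1 higher and 1 lower of 9 (adjusted over the list alone, 1 and 1; camera adjusted p = 0.818), the erythroid and megakaryocyte list 1 higher and 1 lower of 12 (adjusted over the list alone, 1 and 1; camera adjusted p = 0.519) and the stromal and endothelial list 1 higher and 1 lower of 8 (adjusted over the list alone, 1 and 1; camera adjusted p = 0.818). With difamilast the monocyte list had 1 higher and 0 lower of 18 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.791), with a median of -0.06 and a mean of 0.01; its called member Cd14, the lipopolysaccharide co-receptor, went from 267 ± 19.7 to 887 ± 139 CPM (SD, n = 3). The neutrophil list had 0 higher and 1 lower of 18 (adjusted over the list alone, 0 and 2; camera adjusted p = 0.187), with the chemokine receptor gene Cxcr2 1.63-fold lower, and passed without difamilast replicate 3 (adjusted p = 0.0108; 0.0108 to 0.432 over camera's other alternatives at the preset correlation), while all libraries gave adjusted p = 0.505 with an estimated correlation. The dendritic cell list had 1 higher and 2 lower of 13 (adjusted over the list alone, 1 and 2; camera adjusted p = 0.187), the NK and T cell list 0 higher and 1 lower of 16 (adjusted over the list alone, 2 and 1; camera adjusted p = 0.466), the erythroid list 0 higher and 1 lower of 12 (adjusted over the list alone, 0 and 1; camera adjusted p = 0.791) and the progenitor list 1 higher and 1 lower of 12 (adjusted over the list alone, 3 and 3; camera adjusted p = 0.531), with Myb 1.87-fold higher. Of 7 eosinophil, 9 B cell and 8 stromal markers, 0 were called with difamilast by edgeR, DESeq2 or limma-voom, and 1, 2 and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.865, 0.745 and 0.715; for eosinophil markers the median was 0.12, the mean -0.07 and the test pointed down). The difamilast lists whose signs also parted were the secretory list (median 0.02, mean -0.00428, test up) the NF-kB list (median -0.06, mean 0.05, test up) and the cytokine list (median 0.02, mean 0.02, test down).

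Of the tests that follow, the one on STAT5 targets and the length correction that other tests rest on were chosen only after the results were seen. Difamilast replicate 3 lay apart from replicates 1 and 2: over 8741 genes the SD of its deviations was 1.47 times the larger of theirs. By the same measure resting replicate 1, which received no drug, had an SD of 0.282, against 0.195 and 0.184 in resting replicates 2 and 3. A library can thus lie apart without the drug, and the ratio alone does not point to a drug response. After a trend with transcript length had been removed from each library, the ratio for difamilast replicate 3 was 1.41 (bootstrap 1.39 to 1.43). This argues against transcript length as the whole cause. Over genes with transcripts of at least 2000 bases that were called without the library in question, replicate 3 showed a median share of 0.754 of the rise (424 genes) and 0.676 of the fall (211 genes), against 0.962 to 1.13 in the other two. Each share used its own set of genes and its own divisor. The fold changes that replicates 1 and 2 were divided by included replicate 3, and those for replicate 3 did not. This widens a gap, so its size is uncertain. The smaller gap was 0.286, and a weaker response to difamilast in the cells of replicate 3 is a candidate explanation. Whether they came from a separate culture is not given in the labels. A mixture with RNA of cells without the drug was not tested and stays open.

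The fall of 264 genes with difamilast was set against the length trend and against weaker stimulation. Of the lowered genes with transcripts under 1500 bases, 70 of 78 (89.7%) were called lower after the length correction. Their median log2 fold change was -0.947 before the correction and -0.818 after it. These genes were picked for their falls, and the correction raised the number of genes called lower from 264 to 406. Kept calls were thus likely in advance. Removal of the average trend left most of the median fall in place, and an effect of length beyond that trend was not tested. Of the lowered genes with longer transcripts, 181 of 181 (100%) were called lower after the length correction. Over genes of those lengths the trend was near flat, with median log2 fold changes of -0.016 to 0.049 across length bins. Those genes could hardly lose their calls, so the kept calls alone add no evidence on length. The 14 STAT5 targets that had risen lost a median share of 0.0138 of their rise (bootstrap -0.0364 to 0.095). The share was 0.544 for the induced genes called lower, which were picked for their fall. An unpicked list was thus likely to lie below it. Over all 3273 genes that stimulation raised, the median share removed was 5.81%, inside that bootstrap range. The range comes from resampling the 14 genes in the same libraries, so it does not measure the spread between samples. Each of these shares also uses the stimulated libraries in both of its fold changes, which can give a positive share with no drug effect. In these libraries the STAT5 values argue against a large loss of stimulation in those targets. A small loss in the difamilast cultures as a whole stays open. The STAT5 test does not cover a loss limited to the IL-33 arm. Of 32 NF-kB feedback and target genes, 28 had risen and 3 fallen with stimulation, with a median log2 fold change of 1.52. With difamilast 6 rose and 5 fell, with a median of -0.06, which argues against a loss across that list. Chemokine genes had a median of -0.58 with difamilast, and of -0.45 with the length trend removed, so a loss in part of the response to the cytokines stays open. IL-3 and IL-33 were given only together, so neither the rises nor a loss can be assigned to either cytokine. That the drug lowers a part of the induced genes may be held as a hypothesis, found and tested on the same libraries.

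Neighbouring genes read in opposite directions were compared with difamilast, and the genes named among them were chosen after their values were seen. This comparison was not among the tests fixed before the data were examined. Of 1597 pairs that start within 1000 bases of each other on opposite strands, 5 were raised together, among them Nek8 with Tlcd1, Synj1 with 4930404I05Rik and Tmem135 with Fzd4. Another 3 pairs were lowered together, for which no random sets were drawn. Random gene sets matched on expression had fewer raised pairs in 99.8% of 10000 draws (mean 0.942, highest 6). For the calls of the fit of all libraries this argues against no coupling beyond expression level. The draws were not repeated for the other fits, so whether it holds there is not known. The number moved with single libraries: it was 3 without stimulated replicate 1 and 2 without any one of stimulated replicates 2 and 3 and difamilast replicates 1 and 2, but 8 without resting replicate 1 and 8 without a filter on low counts, while 2 pairs, Nek8 with Tlcd1 among them, had both members called in all 17 alternatives. Of the 5 pairs, 20% (1, Synj1 with its partner) had overlapping annotated exons, against 38.5% of all pairs, so reads shared between overlapping exons could account for that pair and stay open there. Shared promoter activity is a candidate explanation for the 4 pairs without overlap, as a hypothesis that was not tested. The random gene sets were set against all 5 pairs, the overlapping one included.

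The 6 libraries of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. In 1 of these splits, the real one, 6770 genes changed with stimulation, 735 with difamilast and 7001 between difamilast and resting cells, and 196 induced genes were lowered; the highest of the other splits was 0 by edgeR for each, with at most 781, 1456 and 2308 genes at an unadjusted p under 0.05, against 8826, 3132 and 9011 in the real ones. Every other split mixes both conditions, so a real difference widens the spread within its groups and lowers the calls. A count of 0 there was thus likely in advance. For the camera calls, the real split gave 11 lists with stimulation against at most 9. With difamilast it gave 8 lists against at most 9, and 3 of 10 splits gave as many, the other two being splits that place difamilast replicate 3 with stimulated libraries in vehicle.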
